A study of Mus musculus with 12 samples.

How the data were processed

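The series measured messenger RNA in G1ME cells, a murine megakaryocyte-erythroid progenitor line that lacks GATA1 per the labels, after transduction with the MIGR1 retroviral vector, which carries green fluorescent protein (GFP), or with a GATA1 construct. GFP-positive cells were sorted by flow cytometry at 18 h or 42 h. The labels give 4 groups of 3 arrays each, lettered A, B and C, and describe the triplicates as biological, so the 12 arrays were treated as separate samples. The letters do not say which culture or day a sample came from.

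The deposited values are linear intensities of 45101 probe sets per array, one number per probe set and array, with no count or detection call. The submitters' processing notes name GCRMA and MAS5, without versions and without saying which of these gave the deposited intensity values. The authors' background correction and scaling are therefore not given in the sources used here. Array medians lay between 8.05 and 8.29, and between 29.2% and 29.7% of the probe sets on an array exceeded an intensity of 100, so most probe sets were near the low end of the scale. At that end changes are compressed by the pseudocount. No further normalization was applied. The number of arrays limits the precision of every value. The highest share of identical values between any pair of arrays was 0.0266%, so no array was a copy of another.

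Probe sets were named through a table that pairs them with the platform annotation. It lists 1 gene symbol for 34945 probe sets, several symbols for 932 and none for 9211, and control probe sets were left out. Gene IDs of 34741 of the single-symbol probe sets matched a RefSeq gene table for mouse assembly GRCm38.p6, and 0 symbols needed updating. No genome build is named by the deposited file, so no coordinates are given and that table served only for names and for the order of neighbouring genes. Probe sets with several symbols or none named no gene. About the genes of the lists that have no single-symbol probe set in these tables, nothing is reported here.

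Values were analysed as log2(intensity + 16), a rule fixed together with the design, the gene lists, the rule for named genes and the alternatives before the data were examined. The rule set this transform for linear values, which it took to come from MAS5. Values in log2, which it took to come from GCRMA, would have been used as deposited. The deposited values were linear, so the transform was applied without knowing which of these made them. The probe set with the highest mean over all 12 arrays stood for a gene, and a gene was tested where that probe set exceeded its array's median on at least 3 of the 12 arrays. This left 10759 of 18193 genes. Differences were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) over all 12 arrays in 4 groups, which share 1 estimate of the spread. The tests were two-sided, and adjusted p-values are Benjamini-Hochberg values over the genes tested, with a threshold of 0.05. Fold changes are on the log2(intensity + 16) scale and understate the change of dim genes; where a group lies at the bottom of the scale, the fold depends on the pseudocount. The 4 comparisons were GATA1 against vector at 18 h, the same at 42 h, the difference between these effects (an interaction), and vector at 42 h against vector at 18 h.

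Each comparison was also tested for 18 gene lists with limma's camera, with a preset inter-gene correlation of 0.01, over lists with at least 3 tested members, and adjusted over the lists of that comparison. Each was repeated with an estimated correlation, which is the stricter test here, and with fry. The lists were globins, heme synthesis and iron, erythroid membrane and maturation, megakaryocyte and platelet, GATA factors and partners, stem and progenitor regulators, PU.1 and myeloid, mast cell with basophil and eosinophil, lymphoid, DNA replication and mitosis, cyclin D and CDK inhibitors, ribosome biogenesis and MYC targets, autophagy and mitochondrial clearance, interferon response, p53 targets, immediate early and heat shock, glycolysis, and cholesterol synthesis. Some genes belong to more than 1 list: 8 of the 15 tested GATA factors and partners, 6 of the 24 stem and progenitor regulators and 5 of the 24 erythroid genes are also in another list.

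Genes were named by a fixed rule. For each comparison of GATA1 with vector these were Gata1, Gata2 and Spi1, the 8 largest rises and 8 largest falls past the threshold whose arrays did not overlap between the groups (clone-type names left out), and up to 2 members rising and 2 falling most per list. For the interaction and for vector over time the rule took 5 in each direction and the same number per list. A list without a member past the threshold could be illustrated by its 2 brightest members, given as values. Any gene named outside this rule is said to have been chosen after its values were seen.

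The replicate letters were tested for pairing. Deviations from the group means correlated between same-letter arrays of vector and GATA1 at 18 h with r of 0.66, 0.31 and 0.65 for A, B and C, at 42 h with 0.60, 0.24 and 0.33, and between vector at 18 h and at 42 h with 0.54, 0.38 and 0.35. The letters therefore pair the arrays in those 3 comparisons, and a fit with the letter as a block is given beside a result where it changes a call or moves a count by more than 1.5 times. For the interaction 1 letter failed the rule, so its block fit is given only with the alternatives. These r values are across genes, which are not independent replicates.

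The tests were checked on simulated data with no group effect except for 200 genes changed at 42 h, over 10759 genes and 5 simulations. The simulated genes and arrays were independent, with no effect of the letters, and far fewer genes changed than the 2253 called at 42 h. The shares below therefore need not hold for the real comparisons. With spreads drawn from limma's fitted prior, 66.0% of genes changed by 0.5 on the log2 scale were recovered, 83.6% of those changed by 1 and 93.9% of those changed by 2, and 4.6% of the calls were false. With each gene's observed SD as its true spread the recovered shares were 50.7%, 89.0% and 97.9%, and 6.6% of the calls were false, so the false share exceeds the nominal level if spreads vary that much between genes. The first version of the simulation used the observed SDs; the second was added after its result was seen.

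Alternatives were no filter and a stricter filter (above the 70th percentile), the mean of a gene's probe sets and every probe set on its own, quantile normalization, median centring, only the arrays compared, the letter as a block, eBayes with trend and robust estimation, array weights, pseudocounts of 1 and 64, a required log2 change of at least 1, and leaving out each array. A further alternative left out the 4 arrays lettered A and was applied to the counts and the lists. It was chosen after the 18S control probe sets were seen to be brighter on them. An exception was vector 18 h replicate B, which also read high in the 5′ 18S probe set (10.6 in log2). For the adjusted p of single lists, only the arrays compared, eBayes with trend and robust estimation, array weights, the estimated correlation and fry were also added after the results were seen. Permutation tests used 10000 permutations.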

Results

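Gene expression was measured on 12 arrays of G1ME cells, a Gata1-negative murine line of megakaryocyte-erythroid progenitors. The cells received either the empty MIGR1 vector, a retrovirus that marks transduced cells with GFP, or a GATA1 construct. GFP-positive cells were sorted at 18 h or 42 h after transduction. GATA1 is a zinc finger transcription factor required for the maturation of red cells and megakaryocytes. Each of the 4 groups had 3 arrays, lettered A, B and C. The comparisons ask which genes respond when GATA1 is supplied to progenitors that lack it, how the response differs between the earlier and the later time, and what changes with time in the vector control. Levels below are deposited linear intensities as the mean ± SD over arrays (n = 3). Changes are differences of mean log2(intensity + 16), given with the SE where an error follows.

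The arrays were alike in level, with medians between 8.05 and 8.29, and their number limits the precision. The highest intensity read 86420 on each of vector 18 h replicate B, GATA1 18 h replicate B and vector 42 h replicate A. The authors may have scaled the arrays to one another, so the alike levels are no check of quality. The log2 ratio of 3′ to 5′ control probe sets lay between 0.38 and 0.55 for beta-actin and between -0.50 and -0.26 for Gapdh on 11 arrays. On GATA1 42 h replicate A these ratios were 0.80 and -0.11. The 5′ probe set for 18S ribosomal RNA read between 8.32 and 12.4 (log2) on arrays lettered A, between 5.53 and 10.6 on those lettered B, and between 4.79 and 6.75 on those lettered C. The highest values were 12.4 on GATA1 42 h replicate A and 10.6 on vector 18 h replicate B.

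The array holds 1 probe set for Gata1. It had an intensity of 3002 ± 284 in vector cells and 2335 ± 91.0 in GATA1 cells at 18 h, and of 3137 ± 116 and 2044 ± 355 at 42 h. It was thus bright in cells described as lacking GATA1 and dimmer where the construct was supplied. The difference was -0.36 ± 0.11 at 18 h (limma adjusted p = 0.227) and -0.63 ± 0.11 at 42 h (limma adjusted p = 0.0034). Where this probe set lies relative to the disrupted part of the endogenous gene or to the construct is not given in the sources used here, so it does not check the labels. The arrays are therefore called GATA1-labelled and vector-labelled, and every direction below rests on those labels.

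At 18 h the genes that rose most in GATA1-labelled cells included genes of red cells and platelets. The embryonic beta-like globin Hbb-y read 58.3 ± 53.9 in vector-labelled and 1063 ± 510 in GATA1-labelled cells, a rise of 3.99 ± 0.49 (limma adjusted p = 0.0035). Klf1, an erythroid transcription factor, went from 240 ± 78.2 to 1859 ± 92.1 (2.92 ± 0.20, adjusted p = 2.64e-04). Epor, the erythropoietin receptor, went from 40.0 ± 17.3 to 186 ± 15.2 (1.89 ± 0.24, adjusted p = 0.0036). Thbs1, which encodes the thrombospondin of platelet granules, rose by 3.31 and Tubb1, the beta-tubulin of platelets, by 1.88. The other large rises were those of Tmem184a (2.22), the cytokine gene Il1b (2.05) and the peptidylarginine deiminase gene Padi3 (1.90). Kit, the receptor for stem cell factor, fell from 349 ± 64 to 98.5 ± 17.4 (-1.67 ± 0.21, adjusted p = 0.0037). Fcgr3, an Fc receptor of myeloid cells, fell from 2246 ± 241 to 770 ± 67.8 (-1.52 ± 0.13, adjusted p = 0.0012). Clec4e, Gpr171, Gcnt2, Rgs2, Cd69 and Cd53 made up the rest of the 8 largest falls, with changes between -2.05 and -1.36.

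Gata2, a GATA factor of progenitors, and Spi1 (PU.1), a regulator of myeloid fate, did not pass the test at 18 h. Gata2 read 2854 ± 933 in vector-labelled and 2497 ± 798 in GATA1-labelled cells (-0.19 ± 0.31, limma adjusted p = 0.9999). Spi1 read 330 ± 47.1 and 234 ± 59.7 (-0.49 ± 0.24, adjusted p = 0.5999).

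In all, 199 of the 10759 genes tested differed between GATA1-labelled and vector-labelled cells at 18 h by limma, 118 higher and 81 lower. Of these, 67 changed at least 2-fold, 47 higher and 20 lower. All 199 changed in the same direction within each of the 3 letters. This is no further support, since the genes were called on these same arrays. For all 199 the arrays of the 2 groups did not overlap, which fixes the direction within each letter. With the replicate letter as a block 355 genes differed (188 higher, 167 lower), 189 of them among the 199. The count was 119 with no filter on low values, 54 with only the arrays compared, and 32 without the 4 arrays lettered A, an alternative chosen after the 18S values were seen. It was 116 without vector 18 h replicate A, 116 without vector 18 h replicate B, 101 without GATA1 18 h replicate A and 120 without GATA1 18 h replicate B.

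Of the 28 genes named here that passed at 18 h, 20 lost the call with only the arrays compared, among them Hbb-y, Thbs1 and Epor, and 8 did not (Klf1, Il1b, Tubb1, Kit, Fcgr3, Ikzf1, Ifi47 and Egr1). Not all of the 28 could be checked in a second probe set, since some, such as Klf1 with 1 probe set, had none to test. In their second brightest probe set 6 of the 28 did not pass (Clec4e, Kit, Rgs2, Ikzf1, Csf2rb and Jun). That of Kit read 36.8 and 20.3 at 18 h (adjusted p = 0.704, against a range of 6.32e-04 to 0.704 over its alternatives). Of the 28, 12 lost the call on leaving out at least 1 array. These were Padi3, Gpr171, Rgs2, Cd53, Cpox, Ppox, Lyl1, Ikzf1, Csf2rb, Irf1, Jun and Ier3, with an adjusted p of up to 0.163 for Jun without vector 18 h replicate A.

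**Figure D1:**
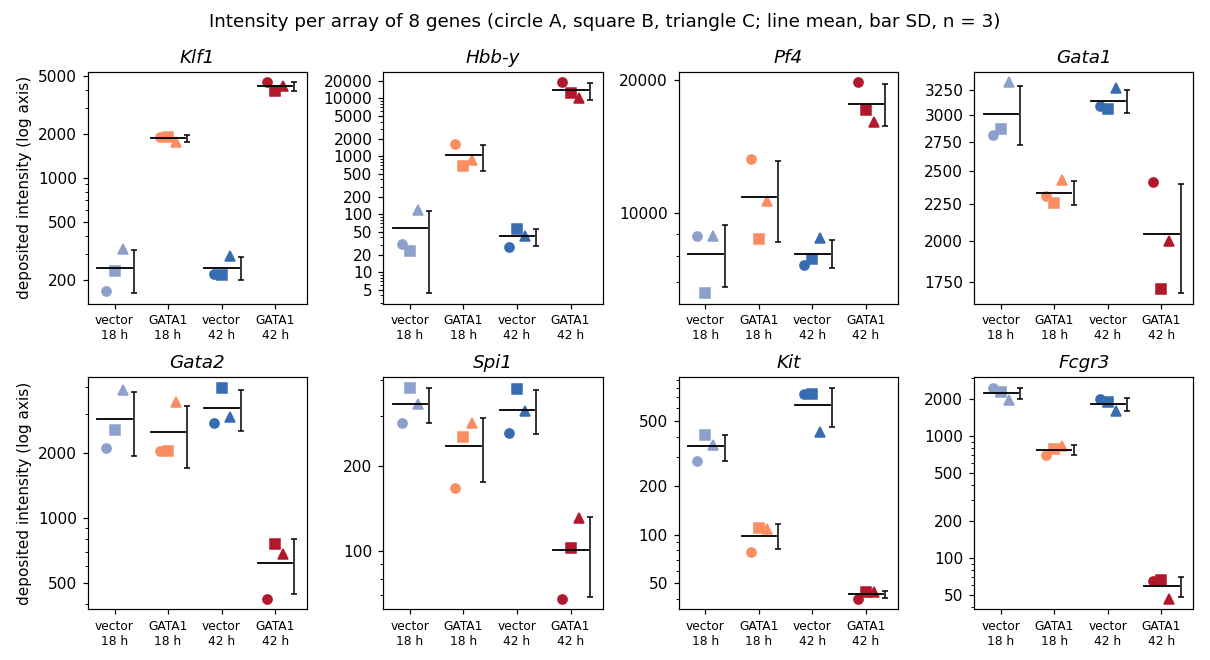
Deposited intensity (log axis) of 8 genes on each of the 12 arrays, by group. Symbols mark the replicate letter, the line is the mean and the bar the SD (n = 3). Klf1 and Hbb-y were brighter on every GATA1-labelled array than on every vector-labelled array of the same time, and the Gata1 probe set was dimmer.

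Lists of red cell and platelet genes rose at 18 h. Of 17 heme synthesis and iron genes 5 rose (7 adjusted over the list alone), with a median change of 0.33 (camera adjusted p = 1.03e-09, adjusted p = 0.0314 with an estimated correlation). Cpox, an enzyme of heme synthesis, went from 850 ± 321 to 2228 ± 560 (1.41 ± 0.28, limma adjusted p = 0.0407), and Ppox, the next enzyme of that pathway, rose by 0.66. Of 24 erythroid membrane and maturation genes 5 rose (7 adjusted over the list alone), Klf1 and Epor among them, with a median of 0.20 (camera adjusted p = 3.93e-10, adjusted p = 0.0314 with an estimated correlation). Of 34 megakaryocyte and platelet genes 6 rose (12 adjusted over the list alone), Thbs1 and Tubb1 among them, with a median of 0.22 (camera adjusted p = 1.23e-11, adjusted p = 0.0314 with an estimated correlation). With the replicate block and an estimated correlation the heme list still passed (adjusted p = 0.0180), while the erythroid list (adjusted p = 0.0569) and the megakaryocyte list (adjusted p = 0.157) did not.

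A further 5 lists passed at 18 h with the preset correlation, and none of these passed with an estimated one. Of 5 globins 1, Hbb-y, rose (2 adjusted over the list alone; camera adjusted p = 0.0163, adjusted p = 0.194 with an estimated correlation). The median of the globins, -0.002, differed in sign from their mean, 1.27, and from the direction of the test, which was upward. Of 15 GATA factors and partners 3 rose and 1 fell (3 and 2 adjusted over the list alone; camera adjusted p = 0.0243, adjusted p = 0.322 with an estimated correlation). Lmo2, a partner of GATA factors, rose by 1.35, and Lyl1, a basic helix-loop-helix factor, fell by 0.41. Of 34 PU.1 and myeloid genes 4 fell and 1 rose (4 and 2 adjusted over the list alone), with a median of -0.16 (camera adjusted p = 0.0122, adjusted p = 0.305 with an estimated correlation). The member that rose was Csf2rb, the common beta subunit of the IL-3 and GM-CSF receptors, from 7588 ± 2409 to 15266 ± 558. Of 26 interferon response genes 1 rose, Ifi47, and 1 fell, Irf1 (1 and 2 adjusted over the list alone), with a median of -0.13 (camera adjusted p = 0.0122, adjusted p = 0.305 with an estimated correlation). Of 49 DNA replication and mitosis genes 0 passed limma's test over all genes or adjusted over the list alone, while camera called the list higher (median 0.04, adjusted p = 0.0127, adjusted p = 0.412 with an estimated correlation). Its brightest members, Pcna and Mcm5, differed by -0.01 and -0.02.

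None of these 5 lists passed with fry either (adjusted p between 0.0576 and 0.411), and 4 of the calls, all but that of the globins, rested on single arrays. The globin call ended with only the arrays compared (camera adjusted p = 0.0853) or without the 4 arrays lettered A (0.0852), over a range of 0.0051 to 0.194. The call of the GATA factors ended without vector 18 h replicate A (adjusted p = 0.1565, where the median was -0.02), GATA1 18 h replicate C (0.1562, median -0.02) or GATA1 42 h replicate A (0.0587). It also ended with only the arrays compared (0.0947), with array weights (0.0567) or without the 4 arrays lettered A (0.110), over a range of 0.0020 to 0.322. The PU.1 and myeloid call ended without vector 18 h replicate C (adjusted p = 0.168), without GATA1 18 h replicate A (0.0935) or with no filter (0.0911), over a range of 7.94e-04 to 0.305. The interferon call ended without vector 18 h replicate C (adjusted p = 0.0552), without GATA1 18 h replicate A (0.0643), without the 4 arrays lettered A (0.0852), with no filter (0.0911) or with a stricter one (0.103), over a range of 0.0013 to 0.305. The DNA replication call ended without GATA1 18 h replicate A (adjusted p = 0.366) or vector 18 h replicate C (0.323, median -0.02), over a range of 7.03e-07 to 0.412.

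The other 10 lists did not pass at 18 h, with camera adjusted p between 0.121 and 0.847. Of 24 stem and progenitor regulators 2 rose and 3 fell (3 and 4 adjusted over the list alone; camera adjusted p = 0.351). Slamf1, a surface marker of stem cells, rose by 1.65 and Ikzf1, the lymphoid regulator Ikaros, fell by 0.41. Of 18 immediate early and heat shock genes 1 rose and 3 fell (2 and 5 adjusted over the list alone; camera adjusted p = 0.141). Egr1, an immediate early transcription factor, went from 727 ± 122 to 1669 ± 143 (1.19 ± 0.17, limma adjusted p = 0.0067), while Jun fell by 0.86 and Ier3 by 0.78. Under the replicate block, ribosome biogenesis and MYC targets passed as higher (camera adjusted p = 0.0439, range 2.47e-04 to 0.967) and cholesterol synthesis as lower (0.0168, range 0.0168 to 0.967). Neither passed with the block and an estimated correlation together (adjusted p = 0.368 and 0.157). Both also passed without vector 18 h replicate B and without GATA1 18 h replicate A. With no filter 10 lists passed, 6 of the 8 among them, and the others were ribosome biogenesis, D cyclins and CDK inhibitors, and glycolysis as higher and the mast cell list as lower. Immediate early genes passed as lower with a stricter filter, and glycolysis as higher without vector 18 h replicate C or GATA1 18 h replicate B. The ranges were 0.0054 to 0.546 for D cyclins and CDK inhibitors, 0.0053 to 0.977 for glycolysis, 0.0174 to 0.307 for the mast cell list and 0.0051 to 0.563 for immediate early genes. None of the 10 lists passed with an estimated correlation. The replicate block also ended the calls of Jun (limma adjusted p = 0.0630, range 0.0150 to 0.332) and Csf2rb (at the threshold itself, range 0.0044 to 0.295), and it added a call for the mast cell gene Cpa3 (0.0071, range 0.0071 to 0.208). In that fit 10 megakaryocyte and platelet genes rose, against 6. Where no gene had passed, it had 1 rise each for DNA replication and mitosis, for D cyclins and CDK inhibitors, and for cholesterol synthesis, and 1 fall each for p53 targets and cholesterol synthesis.

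At 42 h the largest rises again included those of red cell and platelet genes, and mast cell and myeloid genes were among the largest falls. Hbb-y read 41.7 ± 13.8 in vector-labelled and 13812 ± 4528 in GATA1-labelled cells, a rise of 7.88 ± 0.49 (limma adjusted p = 5.10e-06). Hbb-bh1, another embryonic globin, went from 380 ± 224 to 15825 ± 1387 (5.53 ± 0.73, adjusted p = 5.62e-04). Car1, a red cell carbonic anhydrase, went from 6.3 ± 0.1 to 2130 ± 306 (6.58 ± 0.11, adjusted p = 1.16e-09), and Hba-x, an embryonic alpha-like globin, from 3.9 to 1252 ± 430 (5.93 ± 0.21, adjusted p = 1.62e-07). Thbs1 rose by 5.69 and Vwf, the von Willebrand factor of platelet granules, by 5.34, and Ces2g and Cldn13 rose by 5.94 and 5.04. Car1, Hba-x, Vwf, Ces2g and Cldn13 lay at the bottom of the scale in vector-labelled cells, so the size of their change depends on the pseudocount. Cpa3, the mast cell carboxypeptidase, fell from 2008 ± 541 to 49.9 ± 15.9 (-4.94 ± 0.24, adjusted p = 1.08e-06) and Fcgr3 from 1830 ± 218 to 59.3 ± 11 (-4.62 ± 0.13, adjusted p = 3.37e-08). Kit fell from 631 ± 173 to 42.9 ± 2.2 (-3.42 ± 0.21, adjusted p = 4.71e-06). Gcnt2, Clec4e, Crisp3, Cd244a and Perp made up the rest of the 8 largest falls, with changes between -4.70 and -3.19.

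Both Gata2 and Spi1 were lower in GATA1-labelled cells at 42 h. Gata2 read 3208 ± 679 in vector-labelled and 623 ± 176 in GATA1-labelled cells (-2.36 ± 0.31, limma adjusted p = 5.39e-04). Spi1 read 315 ± 55.4 and 101 ± 31.7 (-1.53 ± 0.24, adjusted p = 0.0016).

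In total 2253 of 10759 genes, 20.9%, differed at 42 h by limma, 1113 higher and 1140 lower, and 534 changed at least 2-fold (251 higher, 283 lower). Of the 2253, 2251 changed in the same direction within each letter. For 2239 of them the arrays of the 2 groups did not overlap, which fixes that direction, so it is no further support. Of the 66 genes named here that passed at 42 h, 9 lost the call on leaving out at least 1 array. These were Arhgef6, Cd79b, Lig1, Mcm6, Atg4d, Sqstm1, Ulk1, Xpc and Mvk, with an adjusted p of up to 0.144 for Lig1 without GATA1 42 h replicate B. Named genes without a second tested probe set could not be checked in this way. In their second brightest probe set 14 of the named genes missed the threshold, among them Clec4e (adjusted p = 0.0665, range 1.44e-07 to 0.0665) and Ikzf2 (0.128, range 3.03e-06 to 0.128). From the highest adjusted p down, the others were Mcm6, Rtp4, Rb1, Aldoc, Ulk1, Bcl2l1, Wipi1, Pfkp, Nbeal2, Zap70, Rbl2 and Apex1. The adjusted p was 0.9933 for Mcm6 (range 0.0087 to 0.9933), 0.4717 for Rb1 (range 6.27e-05 to 0.4717) and 0.0692 for Apex1 (range 8.56e-04 to 0.0692). The changes given here for these 14 genes are those of the brightest probe set.

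**Figure D2:**
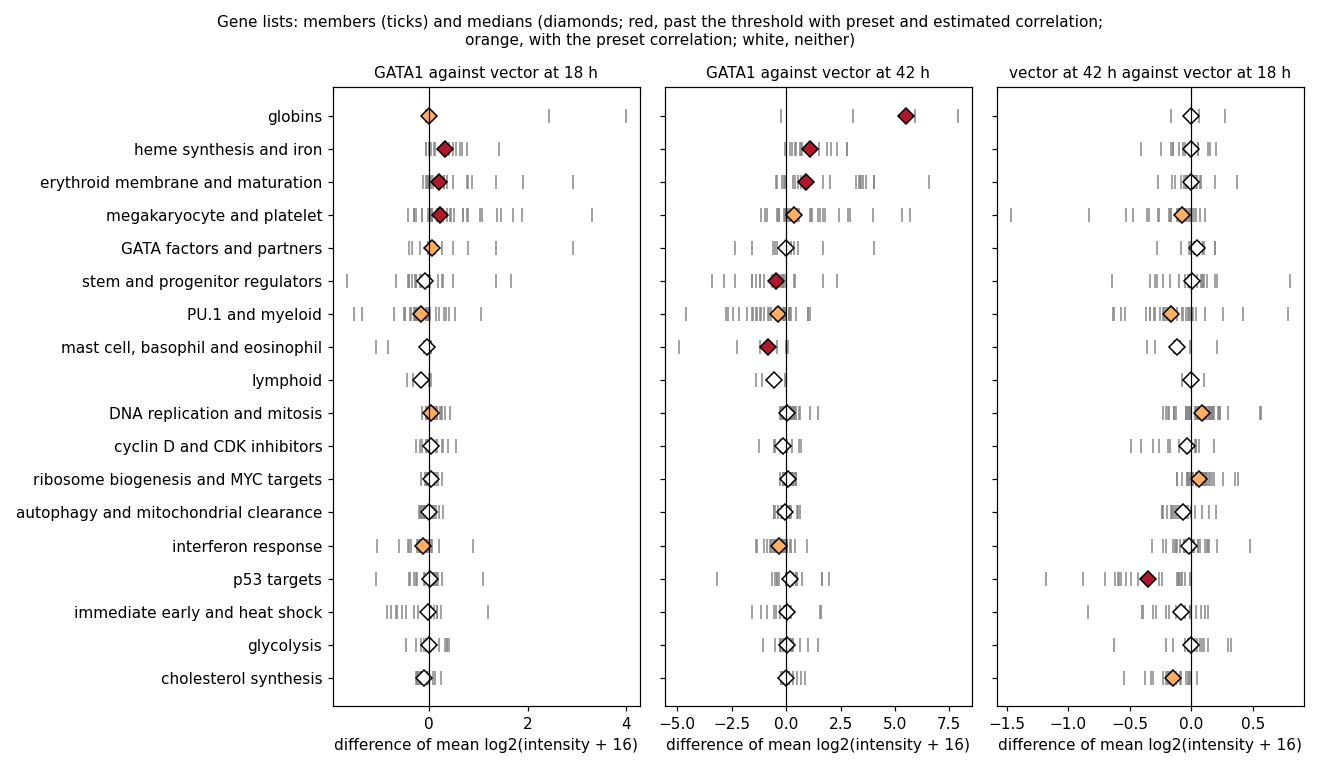
Differences of mean log2(intensity + 16) for the tested members (ticks) of 18 gene lists and their medians (diamonds), in GATA1 against vector at 18 h, at 42 h, and in vector at 42 h against 18 h. Red marks lists past the camera threshold with the preset and the estimated correlation, orange with the preset one, and white neither. The median of heme synthesis and iron was 0.33 at 18 h and 1.09 at 42 h, and that of p53 targets was -0.35 in vector over time.

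The erythroid lists rose at 42 h. Of 17 heme synthesis and iron genes 15 rose (15 adjusted over the list alone), with a median of 1.09 (camera adjusted p = 3.21e-11, adjusted p = 0.0170 with an estimated correlation). Blvrb, a biliverdin reductase, went from 499 ± 103 to 3511 ± 366 (2.79 ± 0.14, limma adjusted p = 1.42e-06) and Cpox rose by 2.77. Of 5 globins 4 rose (4 adjusted over the list alone), with a median of 5.53 (camera adjusted p = 2.51e-05, adjusted p = 0.0195 with an estimated correlation). Of 24 erythroid membrane and maturation genes 17 rose and 2 fell (18 and 2 adjusted over the list alone), with a median of 0.92 (camera adjusted p = 4.39e-11, adjusted p = 0.0195 with an estimated correlation). Klf1 went from 242 ± 43.0 to 4231 ± 271 (4.05 ± 0.20, limma adjusted p = 1.04e-06). The members that fell were Car2, a carbonic anhydrase, by 0.45, and Bcl2l1, an inhibitor of apoptosis, by 0.41. Of 34 megakaryocyte and platelet genes 16 rose and 5 fell (16 and 6 adjusted over the list alone), with a median of 0.35 (camera adjusted p = 2.18e-05, adjusted p = 0.108 with an estimated correlation). Besides Thbs1 and Vwf, the named members were Arhgef6, a guanine nucleotide exchange factor, and Nbeal2, a gene of platelet alpha granules, which fell by 1.17 and 0.97.

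Progenitor, myeloid, mast cell and interferon lists were lower at 42 h. Of 24 stem and progenitor regulators 11 fell and 2 rose (13 and 2 adjusted over the list alone), with a median of -0.48 (camera adjusted p = 2.51e-05, adjusted p = 0.0170 with an estimated correlation). Ikzf2, the Ikaros family gene Helios, fell by 2.86, and the members that rose were Slamf1, by 2.32, and Lmo2, by 1.68. Of 34 PU.1 and myeloid genes 14 fell and 3 rose (18 and 3 adjusted over the list alone), with a median of -0.39 (camera adjusted p = 1.30e-05, adjusted p = 0.0604 with an estimated correlation). Tyrobp, a signalling adaptor of myeloid cells, fell from 1072 ± 80.1 to 147 ± 48.5 (-2.78 ± 0.25, limma adjusted p = 5.00e-05), while the integrin gene Itgb2 and the neutrophil protease gene Prtn3 rose by 1.09 and 0.99. Of 6 mast cell, basophil and eosinophil genes 4 fell and 0 rose (4 and 0 adjusted over the list alone), with a median of -0.81 (camera adjusted p = 0.0042, adjusted p = 0.0463 with an estimated correlation). One of them was Slc18a2, the vesicular monoamine transporter, which fell by 2.24. Of 26 interferon response genes 12 fell and 1 rose (12 and 1 adjusted over the list alone), with a median of -0.31 (camera adjusted p = 5.73e-04, adjusted p = 0.157 with an estimated correlation). The immunoproteasome gene Psmb8 fell by 1.34, Rtp4 fell by 1.39, and Ifi47 rose by 0.94.

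With the replicate block and an estimated correlation together, heme synthesis and iron was the 1 list that passed at 42 h (adjusted p = 0.0134), and globins (0.107), the erythroid list (0.0547), stem and progenitor regulators (0.0804) and the mast cell list (0.135) did not. With no filter on low values, which adds dim members, the mast cell median was 0.001 and its call ended (camera adjusted p = 0.537, range 1.59e-06, with fry, to 0.537).

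The other 10 lists did not pass at 42 h. Of 15 GATA factors and partners 3 rose, Klf1 and Lmo2 among them, and 3 fell, Gata2 and Lyl1 among them (3 and 3 adjusted over the list alone; camera adjusted p = 0.872). Of 49 DNA replication and mitosis genes 7 rose and 2 fell (7 and 2 adjusted over the list alone; camera adjusted p = 0.141). E2f2, a cell cycle transcription factor, rose by 1.44 and Ccne1, cyclin E1, by 1.09, while Lig1, a DNA ligase, and the helicase subunit Mcm6 fell by 0.27 and 0.25. The call of Lig1 ended with the replicate block (limma adjusted p = 0.0573, range 0.0109 to 0.144). Of 20 p53 targets 6 rose and 4 fell (8 and 4 adjusted over the list alone; camera adjusted p = 0.402), with Eda2r and Zmat3 up by 1.98 and 1.63, while Perp fell by 3.19 and Xpc by 0.67. Of 15 genes for D cyclins and CDK inhibitors 2 rose and 3 fell (2 and 4 adjusted over the list alone; camera adjusted p = 0.485). Rb1, the retinoblastoma gene, rose by 0.69 and Cdkn2c by 0.59, and Cdkn1c, a CDK inhibitor, fell by 1.24 and Rbl2 by 0.58. Of 17 glycolysis genes 3 rose and 1 fell (3 and 1 adjusted over the list alone; camera adjusted p = 0.612), with the phosphofructokinases Pfkm and Pfkp up by 1.47 and 0.98, while Aldoc fell by 1.05. Of 19 cholesterol synthesis genes 2 rose, Ebp by 0.88 and Mvk by 0.68 (2 adjusted over the list alone; camera adjusted p = 0.485).

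In the list of autophagy and mitochondrial clearance 3 of 23 genes rose and 2 fell at 42 h (3 and 2 adjusted over the list alone; camera adjusted p = 0.872). Wipi1 and Atg4d rose by 0.64 and 0.48, while the autophagy receptor gene Sqstm1 fell by 0.57 and the kinase gene Ulk1 by 0.55. Of 18 immediate early and heat shock genes 2 rose and 4 fell (2 and 4 adjusted over the list alone; camera adjusted p = 0.872). The heat shock gene Hspa1b and the phosphatase gene Dusp1 rose by 1.61 and 1.55, and Jund fell by 1.56 and Ier2 by 1.17. Of 4 lymphoid genes 2 fell (2 adjusted over the list alone; camera adjusted p = 0.149), the T cell kinase gene Zap70 by 1.37 and Cd79b of the B cell receptor by 1.10. Of 39 ribosome biogenesis genes and MYC targets 5 rose and 1 fell (5 and 1 adjusted over the list alone; camera adjusted p = 0.0521). Odc1, ornithine decarboxylase, rose by 0.47 and Noc3l by 0.44, and Apex1, a DNA repair enzyme, fell by 0.31. The lymphoid list passed as lower with the replicate block (camera adjusted p = 0.0453, range 0.0147, with fry, to 0.810), and the ribosome list as higher (0.0119, range 0.0041 to 0.616). Neither passed with an estimated correlation, be it without the block (adjusted p = 0.495 and 0.616) or with it (0.163 and 0.340). In that fit 11 ribosome biogenesis genes and MYC targets rose, against 5, as did 4 cholesterol synthesis genes, against 2, and 2 interferon response genes, against 1, while 3 glycolysis genes fell, against 1. The ribosome list also passed with only the arrays compared (0.0381), with array weights (0.0327) and without the 4 arrays lettered A (0.0041), and in 5 of the 12 fits that leave out 1 array. DNA replication and mitosis passed as higher without the 4 arrays lettered A, and D cyclins and CDK inhibitors as lower with fry. With an estimated correlation these 2 lists did not pass (camera adjusted p = 0.648 and 0.616).

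The genes called at 18 h were mostly called in the same direction at 42 h. The group means came from other arrays, but the 2 sets of calls are not independent. Both used 1 estimate of the spread over all 12 arrays, and the letters pair vector arrays between the times (r of 0.54, 0.38 and 0.35). Of the 118 genes higher at 18 h 111 were higher at 42 h, where independent lists would share 12.2. Of the 81 lower genes 76 were lower at 42 h, where independent lists would share 8.58 (Fisher's exact test, two-sided, p = 6.93e-102 and 1.26e-68). Fisher's test treats the genes and the 2 sets of calls as independent, which they are not. Across all tested genes the changes at the 2 times correlated with a Pearson's r of 0.717 and a Spearman's rho of 0.528, and across the genes called at 18 h with r of 0.922. These are correlations across genes, which are not independent replicates. Siglecf, a sialic acid-binding lectin of myeloid cells, chosen after its values were seen, was the 1 gene called in opposite directions. It was higher by 0.88 ± 0.17 at 18 h and lower at 42 h by -0.77 ± 0.17 (limma adjusted p = 0.0368 and 0.0111).

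**Figure D3:**
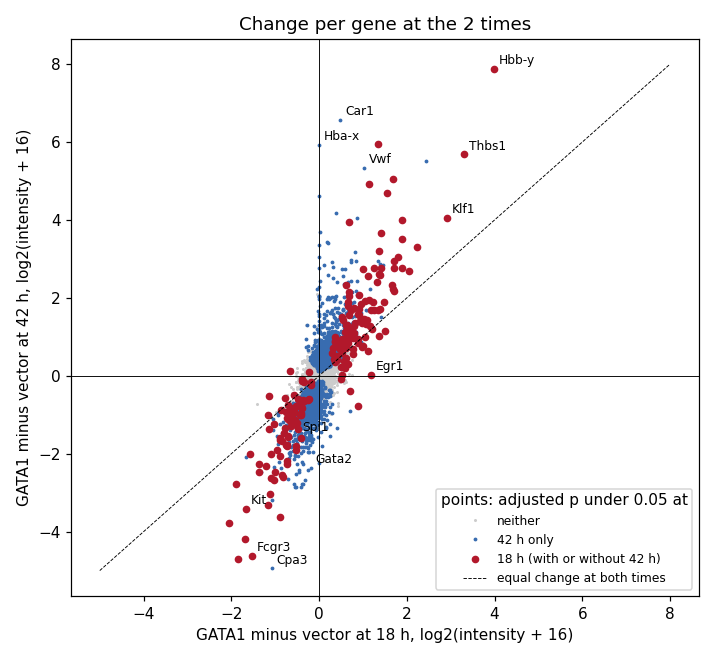
Change per gene, GATA1 minus vector in log2(intensity + 16), at 18 h (x axis) and 42 h (y axis), for the 10759 genes tested. Red points were called at 18 h, blue points at 42 h only, grey points at neither time, and the dashed line marks equal change. Hbb-y, Thbs1 and Klf1 lie above the dashed line among the genes that rose, and Cpa3 and Fcgr3 below it among those that fell.

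Some globin, heme and erythroid genes had larger rises, and some mast cell, myeloid and progenitor genes larger falls, at 42 h than at 18 h. The largest positive differences between the GATA1 effects were those of Car1 (6.09 ± 0.16), Hba-x (5.93 ± 0.30), the amino acid transporter gene Slc38a5 (4.62 ± 0.10), Ces2g (4.59 ± 0.15) and Vwf (4.31 ± 0.42). All 5 lay at the bottom of the scale in vector-labelled cells. The largest negative differences were those of Cpa3 (-3.86 ± 0.34), Fcgr3 (-3.10 ± 0.19), Gcnt2 (-2.85 ± 0.31), Crisp3 (-2.72 ± 0.16) and Ikzf2 (-2.44 ± 0.35). Over these 10 genes limma's adjusted p for the interaction lay between 1.94e-08 and 0.0047. Where a second probe set was tested, 5 of the genes named for the interaction lost the call in it. These were Gcnt2 (limma adjusted p = 0.0628), Ikzf2 (0.550), Psmb8 (0.591), Socs3 (0.299) and Odc1 (0.129).

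The interaction was past the threshold for 504 of 10759 genes by limma, 248 with a more positive and 256 with a more negative effect at 42 h. Of the 504, 400 changed in the same direction at both times with the larger size at 42 h, 498 were called at 42 h and 82 at 18 h. Gata2 differed by -2.17 ± 0.43 (adjusted p = 0.0227), a call that ended without vector 18 h replicate A (0.0520), vector 18 h replicate B (0.0617) or vector 42 h replicate B (0.0567), over a range of 0.0070 to 0.0617. Egr1, higher at 18 h, differed by 0.03 at 42 h, and its interaction was -1.16 ± 0.24 (adjusted p = 0.0236, range 0.0108 to 0.0655). That call ended on leaving out 1 array in 6 cases, most clearly without GATA1 18 h replicate C (0.0655). The other named calls that ended without at least 1 array were those of Car2, Prtn3, Itgb2, Psmb9, Eda2r and Socs3. The count was 320 with no filter, 324 without GATA1 18 h replicate B, 326 without GATA1 18 h replicate C, and 258 without the 4 arrays lettered A.

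For 8 lists the GATA1 effect differed between the times. Effects were more positive at 42 h for 3 of 5 globins (4 adjusted over the list alone; median difference 3.10, camera adjusted p = 2.29e-06) and 6 of 17 heme synthesis and iron genes (8 adjusted over the list alone; 0.61, adjusted p = 8.14e-10). They were more positive for 12 and more negative for 1 of 24 erythroid genes (14 and 3 adjusted over the list alone; 0.68, camera adjusted p = 3.21e-09). Besides Car1 these included Tspan33, a tetraspanin gene, with a difference of 3.67, and the heme list included Blvrb (2.46) and Alas2, the erythroid enzyme that starts heme synthesis (2.04). For megakaryocyte and platelet genes they were more positive for 8 of 34 (10, and 2 more negative, adjusted over the list alone; 0.21, camera adjusted p = 0.0188), among them the serotonin transporter gene Slc6a4 (2.41). Effects were more negative at 42 h for 9 of 24 stem and progenitor regulators (9 adjusted over the list alone; -0.51, camera adjusted p = 2.62e-07). They were more negative for 8 and more positive for 2 of 34 PU.1 and myeloid genes (13 and 2 adjusted over the list alone; -0.36, camera adjusted p = 5.65e-07), with Tyrobp at -2.41. They were more negative for 3 of 6 mast cell genes (3 adjusted over the list alone; -0.41, camera adjusted p = 0.0041) and 3 of 26 interferon response genes (4 adjusted over the list alone; -0.18, adjusted p = 0.0056). Of the 8 lists 6 passed with an estimated correlation, with adjusted p between 0.0093 and 0.0363, and megakaryocyte genes (adjusted p = 0.361 with an estimated correlation) and interferon genes (adjusted p = 0.272 with an estimated correlation) did not. The megakaryocyte call also ended without vector 18 h replicate C (adjusted p = 0.112), without vector 42 h replicate A (0.0830), without the 4 arrays lettered A (0.0605), with no filter (0.207) or with a stricter one (0.334), over a range of 0.0037 to 0.361. The interferon call also ended with fry (0.0886, range 8.52e-05 to 0.272). Cholesterol synthesis, GATA factors, D cyclins and CDK inhibitors, ribosome biogenesis and lymphoid genes passed under at least 1 alternative, and none of them with an estimated correlation. With no filter the mast cell median was 0.005 and its call ended (adjusted p = 0.906, range 2.81e-05 to 0.906).

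In vector-labelled cells p53 targets were lower at 42 h than at 18 h as a list, and few single genes passed. All 20 tested p53 targets had lower means at 42 h, with a median of -0.35 (camera adjusted p = 7.11e-11, adjusted p = 0.0110 with an estimated correlation). The sizes were uneven, from -1.19 ± 0.24 for Trp53inp1 to -0.01 ± 0.03 for Pmaip1, and several were smaller than their SE. Pmaip1, chosen after its values were seen, read 8.6 and 8.4, at the bottom of the scale. None of the 20 passed over all genes by limma, and 7 fell when adjusted over the list alone. Under the replicate block 2 of the 20 fell, Ccng1 and Trp53inp1, the latter chosen after its values were seen. Ccng1, cyclin G1, read 12337 ± 1180 at 18 h and 8529 ± 652 at 42 h (-0.53 ± 0.08, limma adjusted p = 0.101). Cdkn1a, the CDK inhibitor p21, read 3385 ± 118 and 2421 ± 339 (-0.49 ± 0.13, adjusted p = 0.433).

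By limma 2 of 10759 genes differed between 42 h and 18 h in vector-labelled cells, both lower, against 676 at an unadjusted p under 0.05. Trp53inp2, a gene linked to autophagy, went from 35.3 ± 1.8 to 13.9 ± 2.3 (-0.78 ± 0.06, adjusted p = 0.0048), and Mpp1, a red cell membrane protein gene, from 601 ± 16.1 to 460 ± 10 (-0.38 ± 0.04, adjusted p = 0.0399). Fitted with the replicate block, 41 genes differed, 4 higher and 37 lower, and these 2 were among them. The block called Ccng1 (adjusted p = 0.0113, range 0.0113 to 0.565) and Plek, the platelet protein pleckstrin (0.0409, range 0.0409 to 0.640). Within the lists it had 2 falls each for megakaryocyte, p53 and cholesterol genes and 1 for D cyclins and CDK inhibitors, where none had passed. With only the arrays compared neither Trp53inp2 (0.551, range 0.0011 to 0.551) nor Mpp1 (0.551, range 0.0252 to 0.551) passed. The call of Mpp1 also ended on leaving out any 1 of the 12 arrays, with an adjusted p of up to 0.178 without vector 42 h replicate A.

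The remaining lists that passed over time in vector-labelled cells had 0 members past limma's threshold over all genes. Lower at 42 h were PU.1 and myeloid genes (median -0.16, 3 adjusted over the list alone; camera adjusted p = 2.38e-05, adjusted p = 0.188 with an estimated correlation) and megakaryocyte and platelet genes (-0.08, 3 adjusted over the list alone; camera adjusted p = 0.0067, adjusted p = 0.262 with an estimated correlation). Cholesterol synthesis was also lower (-0.15, 0 adjusted over the list alone; camera adjusted p = 0.0014, adjusted p = 0.262 with an estimated correlation, but 0.0180 with the replicate block as well). Higher at 42 h were DNA replication and mitosis (0.09, 0 adjusted over the list alone; camera adjusted p = 8.03e-04, adjusted p = 0.262 with an estimated correlation) and ribosome biogenesis and MYC targets (0.07, 0 adjusted over the list alone; camera adjusted p = 2.17e-04, adjusted p = 0.262 with an estimated correlation). Without vector 18 h replicate C the calls of the megakaryocyte (adjusted p = 0.326) and DNA replication lists (0.163) ended, and without vector 18 h replicate A those of the ribosome (0.129) and cholesterol lists (0.185). The megakaryocyte call also ended without vector 42 h replicate A (0.260) and, like the cholesterol call (0.131), with no filter (0.354). None of these 5 lists passed with fry (adjusted p between 0.0538 and 0.407). Over all alternatives the ranges were 2.44e-04 to 0.354 for megakaryocyte genes, 8.04e-06 to 0.188 for PU.1 and myeloid genes, 5.15e-09 to 0.407 (with fry) for DNA replication, 2.56e-09 to 0.407 (with fry) for ribosome biogenesis and 1.16e-06 to 0.262 for cholesterol synthesis. Immediate early and heat shock genes also passed as lower with the replicate block (adjusted p = 0.0457, range 0.0239 to 0.447), but not with the block and an estimated correlation together (0.315). The list of autophagy and mitochondrial clearance passed as lower with fry (0.0193), with only the arrays compared (0.0403), with array weights (0.0418) and without the 4 arrays lettered A (0.0409), over a range of 0.0193 to 0.659. It did not pass with an estimated correlation (adjusted p = 0.215, and 0.230 with the block as well). The mast cell list passed as lower with no filter, D cyclins and CDK inhibitors as lower with a stricter one, and glycolysis as higher without vector 18 h replicate C, none of them with an estimated correlation.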

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

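Chosen only after the result was seen were the tests of the splits of the vector arrays over time, of which arrays the interaction splits keep together, of the Gata1 probe set, and of p53 targets in GATA1-labelled cells.

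The GATA1 effect differed between 42 h and 18 h for 504 genes by limma's interaction term, 248 with a more positive and 256 with a more negative effect at 42 h. The largest differences were those of Car1 (6.09), Hba-x (5.93), Slc38a5 (4.62), Ces2g (4.59) and Vwf (4.31), and of Cpa3 (-3.86), Fcgr3 (-3.10), Gcnt2 (-2.85), Crisp3 (-2.72) and Ikzf2 (-2.44). In their second brightest probe set Gcnt2 (limma adjusted p = 0.0628) and Ikzf2 (0.550) did not pass. The lists whose effects differed by camera had median differences of 3.10 (globins), 0.61 (heme synthesis and iron), 0.68 (erythroid), 0.21 (megakaryocyte), -0.51 (stem and progenitor), -0.36 (PU.1 and myeloid), -0.41 (mast cell) and -0.18 (interferon response). The megakaryocyte list (adjusted p = 0.361 with an estimated correlation) and the interferon list (adjusted p = 0.272 with an estimated correlation) did not pass the stricter test. With no filter on low values the mast cell median was 0.005.

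For the interaction, vector and GATA1 were exchanged among the arrays of each time in 100 of the 200 possible splits. As many as 504 genes were called in 6 of the 100, the real one included, and the highest other split called 1212. The 5 other splits with as many genes (1212, 791, 748, 579 and 508) all kept the 3 vector and the 3 GATA1 arrays of 42 h together. Such splits hold the real effect at 42 h, so they are no splits without a difference, and the share of 0.06 does not bear on chance. Of the 93 splits that mixed those arrays the highest called 13 genes. The test is void and decides nothing about how far the times differ.

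The splits of the other comparisons are too few for a share under 0.05. Of the 10 splits of the 6 arrays, 1 gave as many genes at 18 h, the real one with 199, and the highest other gave 1. At 42 h 1 of 10 did, the real one with 2253, and the highest other gave 1. In vector over time 1 of 10 did, the real one with 2, and the highest other gave 0. The 3 other splits that part all 3 letter pairs gave 0 genes in each comparison by limma. Each of the other splits mixes arrays of the groups compared, so a real difference would add to the spread within groups. That alone would keep their counts low, so they do not show what arrays without a difference would give.

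The Gata1 probe set was bright in vector-labelled cells and lower in GATA1-labelled cells. Exchanged labels of whole groups would put heme genes, known GATA1 targets, lower under the GATA1 label, but their median at 42 h was 1.09, which argues against an exchange. Whether the probe set reads the construct was not decided, since the array holds 0 other probe sets of Gata1. A probe set that misses the construct would by itself give no fall. At 42 h the mean intensity was 3137 in vector-labelled and 2044 in GATA1-labelled cells (limma adjusted p = 0.0034). Missing the construct alone therefore does not account for the lower level. A lower endogenous Gata1 transcript where GATA1 is supplied, a biological explanation, stays open and was not tested.

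In vector-labelled cells all 20 tested p53 targets had lower means at 42 h than at 18 h, several of them by less than their SE. A single letter as the cause is argued against, since the medians within letters A, B and C were -0.475, -0.306 and -0.258. An effect of time since transduction that both arms share cannot be told apart from one of the vector arm. In GATA1-labelled cells the median was -0.168 with 13 of 20 lower (camera p = 0.0625 before adjustment, 0.182 with an estimated correlation). The interaction, which compares the change over time between the arms, did not pass for p53 targets (median 0.116, camera adjusted p = 0.102, 0.361 with an estimated correlation). In GATA1-labelled cells the medians within letters A, B and C were -0.162, -0.041 and -0.006, so in that arm the fall lay mostly in letter A. The time itself, a biological explanation, also stays open, since it comes with the time since transduction.

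Among 3245 probe sets outside the gene tests, 196 changed at 42 h by limma (76 higher, 120 lower), 74 of 600 with several symbols and 122 of 2645 with none listed.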

How the results depend on the processing

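Leaving out the 4 arrays lettered A was chosen only after the 18S values were seen. For single lists, only the arrays compared, eBayes with trend and robust estimation, array weights, an estimated correlation and fry were also added after the results were seen; the other tests here were planned. Each gene or list was counted once per comparison and alternative. For named genes 4143 results kept their side of the threshold, and the call was lost 303 times, gained 12 times and reversed 0 times. The 4143 include results with no call in either fit. Leaving out an array outside the groups compared changes only the estimate of the spread, not the log2 change of a gene. For lists the call was kept 653 times, always in the same direction, lost 59 times and gained 60 times, and 934 results had no call in either. Where there was a call, the sign of the list median changed 14 times. In second brightest probe sets 68 results were the same and 25 lost the call. Quantile normalization and median centring moved the median of all genes by at most 0.018. The array levels were already alike, so these steps had little to move.

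At 18 h, against 199 genes, 119 were called with no filter (118 shared; more genes were tested), 54 with only the arrays compared (48 shared; fewer arrays), 355 with the replicate block (189 shared), 32 without the A arrays (30 shared; fewer arrays). With a log2 change of at least 1, a subset by construction, 67 were left. Leaving out 1 array gave 101 to 200. At 42 h, against 2253, 534 had a log2 change of at least 1, and all other alternatives gave 1685 (only the arrays compared) to 3052 (block), with 1 array left out 1691 to 2221. For the interaction, against 504, the counts were 320 with no filter (317 shared), 853 with the block (492 shared), 258 without the A arrays and 220 with a log2 change of at least 1, and 324 to 539 with 1 array left out. In vector over time, against 2, they were 1 with a stricter filter (0 shared), quantile normalization, median centring or pseudocount 1, 0 with only the arrays compared, without the A arrays or with a log2 change of at least 1 (limma, 676 unadjusted). They were 41 with the block and 1 to 3 with 1 array left out. Fits without an array assume that the remaining arrays of its group vary like the other groups.

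Lists past the threshold, against 8 at 18 h, numbered 3 with an estimated correlation and 3 with fry (6 to 10 with 1 array left out). At 42 h, against 8, 5 passed with an estimated correlation (8 to 9 with 1 array left out), for the interaction, against 8, 6 (8 to 9), and over time in vector, against 6, 1 and 2 with fry (4 to 8). The median of globins at 18 h (-0.002) was 1.213 with a stricter filter, which tests fewer of them, 0.021 with the mean of probe sets, 0.016 with median centring and 0.009 with array weights. It was -0.003 to 0.032 with 1 array left out. Also with 1 array left out, medians at 18 h ran from -0.019 to 0.169 for GATA factors, -0.021 to 0.074 for DNA replication and -0.151 to 0.138 for glycolysis, and that of glycolysis over time in vector from -0.034 to 0.096. With no filter the mast cell median was 0.001 at 42 h (with 1 array left out -0.897 to -0.747) and 0.005 for the interaction (-0.61 to -0.238). Except where fewer arrays, other genes or the construction are named, the cause was not tested.

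For the interaction the letters did not pair by the rule (r of -0.11 and 0.05 for letter B), though 11 of 12 arrays correlated best with an array of their own letter. Its block fit called lymphoid genes (camera adjusted p = 0.0255, range 0.0255 to 0.577) and cholesterol synthesis (0.0095, range 0.0080 to 0.417), and by limma Cd79b (0.0121, range 0.0121 to 0.729) and Zap70 (0.0416, range 0.0416 to 0.712), and ended the megakaryocyte call (0.0733, range 0.0037 to 0.361). With an estimated correlation as well, heme genes passed (0.0153), while globins, the erythroid, stem, PU.1 and mast cell lists (0.0517 to 0.101), lymphoid genes (0.101) and cholesterol synthesis (0.0862) did not. Beyond these and the changes named in the report the block changed no other call of a named gene or list. Signal over background limits what dim genes can show, since 1529 tested genes lay under an intensity of 16 in all 4 groups and 7765 exceeded 100 in at least 1.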

Other observations

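Chosen only after the result was seen were the genes called at 18 h alone and the tests of early shares on genes taken by their mean over all arrays and with other pseudocounts.

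Among genes called at 18 h, 11 were not called at 42 h. Muc13, a mucin of cell membranes, was higher at 18 h by 0.51 (2450 in vector-labelled and 3485 in GATA1-labelled cells) and differed by -0.08 at 42 h (limma's adjusted p of the interaction 0.0245). Parm1 was higher by 0.71 at 18 h and differed by -0.39 at 42 h (interaction 0.0102). Socs3, a suppressor of cytokine signalling, was lower by 0.67 and Gpr19 by 0.24 at 18 h, and they differed by 0.11 and 0.11 at 42 h (interaction 0.0314 and 0.0183). With Egr1, these 5 passed the interaction test, though Socs3 did not in its second brightest probe set (limma adjusted p = 0.299). Bhlhe40, Creb5, Ehbp1, Hyal3, Lpin2 and Mtmr14 did not, so their effect is not shown to differ between the times. Siglecf read 489 and 921 at 18 h, and 280 and 157 at 42 h, in vector-labelled and GATA1-labelled cells.

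Genes that rose at least 2-fold by 42 h had reached a median of 32.3% of that change at 18 h (251 genes), and genes that fell 28.5% (283 genes), a difference of 3.8 percentage points (two-sided permutation p = 0.0604, 10000 permutations). The difference did not pass, nor did it with a pseudocount of 64 (5.3 points, permutation p = 0.0541), but it passed with a pseudocount of 1 (3.4 points, permutation p = 0.0372), so the call depends on the pseudocount. The planned test on genes over 100 in all 4 groups gave 17.6 points, but it is void, since a minimum over the groups removes genes by their change. A test on genes with a mean over 100 across all 12 arrays gave 12.5 points, and the remaining genes gave -18.7, but it is void as well, since that mean holds the level at 18 h and so the share itself. Whether rising genes responded earlier was therefore not decided.

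Genes called at 42 h were next to one another in the order of tested genes along the chromosomes more often than permuted calls. Neighbours here were consecutive tested genes of a chromosome. Untested genes between them were skipped and no limit of distance was set, so a pair need not be adjacent in the genome. Among 9477 neighbouring pairs of 10736 placed genes, 284 were called in the same direction, against a mean of 208 and a highest of 259 in 10000 permutations (one-sided permutation p = 0.0001, the smallest they can give). Pairs called in opposite directions numbered 171, against a mean of 208 (one-sided permutation p = 0.998). Pairs whose symbols share their first 3 letters were left out as planned, and overlapping genes were left out in addition. Neighbours may share control by GATA1, but this was not tested. The distance between neighbours, related genes with other names and probe sets that read both neighbours were not tested either.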
